A study of Homo sapiens with 9 samples.

How the data were processed

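The study used pooled lentiviral libraries in K562 cells, an established human leukaemia line, carrying a reporter gene whose product is captured on magnetic beads. Each cell expressed a fusion of a KRAB repressor domain with 1 element of a library of nuclear protein domains, recruited to the reporter by doxycycline, per the labels. Cells were separated by magnetic beads into a bound and an unbound fraction after 2 days of doxycycline (day 2), and again after 5 days of doxycycline and 5 days of release (day 10), per the labels' protocols. The protocols give 2 separately infected cultures at an average multiplicity of infection of 0.015 and an infection coverage of 85 cells per element, and 32 PCR cycles before sequencing. The headers of the deposited tables say only ON and OFF. ON was read as the bound and OFF as the unbound fraction from knowledge of the assay, in which beads capture the reporter product, and the direction of every ratio rests on that reading. A higher unbound over bound ratio then means more silencing.

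The authors deposited whole-number counts per element for each fraction and replicate, per the file headers. The tools bcl2fastq and Bowtie and the build hg38 are named by the submitters' processing notes, with no versions, and how reads were assigned to elements is not given in the sources used here. The smallest deposited count was 5 in both tables, and between 28 and 355 elements per library sat at exactly 5, so a count of 5 is read as a floor. The log2 scores that the authors deposited per replicate equal the log2 ratio of unbound over bound counts, each divided by its library total; the largest gap between the deposited and recomputed score was 9.08e-09. There were 5614 elements at day 2 and 5599 at day 10, of which 5540 and 5486 had counts in both replicates. A further deposited table lists 2563 domain elements with the authors' calls, their mean log2 scores from other screens, a hydropathy score and a fraction of disorder-promoting residues, per the file headers. Values of single replicates fill 68 of its columns, 52 from other screens and 16 that repeat this screen, and none of these was used. The unsorted library sample was not analysed here.

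Total counts per library ran from 3896291 to 5760478, with medians per element between 207 and 551. Counts are PCR reads without molecular identifiers, so they are not independent cells.

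Each day was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, Benjamini-Hochberg adjustment over all tested elements, threshold 0.05). The model had a block for the replicate, TMM scaling over the 2 kinds of negative control, and the low-count filter filterByExpr, which left 5495 elements at day 2 and 5431 at day 10. Log2 fold changes are unbound over bound and are given with a standard error (n = 2 replicates per group). It is the absolute fold change over the square root of the test's F statistic. It thus rests on a spread shared across elements and is not the spread of 2 replicates. The difference between days was tested over all 8 libraries on 5463 elements. The replicate block follows the protocols, since both fractions of a number come from 1 infected culture. As a check, deviations from the group mean of the bound and unbound libraries of a number correlated across elements with r = 0.111 at day 2 and 0.125 at day 10.

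Domain lists were written before the data were examined: KRAB, activation domains, HP1 and Polycomb, methyl-DNA binding and NuRD, SUMO and ubiquitin, homeodomain, helix-loop-helix, C2H2 zinc finger, bZIP, HMG box, forkhead, nuclear receptor, corepressor contacts, bromodomain, PHD finger, histone methyltransferase, PWWP and Tudor, RNA binding, random-sequence controls and DMD tile controls. Of these 20 lists, 19 had the minimum of 3 measured members; the forkhead list did not. Lists and Pfam families of at least 5 elements were tested with camera from limma 3.58.1 at a preset correlation of 0.01. Camera compares a list with all other elements, controls included. They were tested again with a correlation estimated from the residuals of the fit. Each day leaves 1 residual degree of freedom and the difference 2, so hardly any list could pass that second test. A failure there therefore decides nothing. Random sequences and DMD tiles were compared by a two-sided permutation test with 100000 resamples on the mean log2 ratio of the replicates, with a pseudocount of 1. Elements and not cultures were permuted, so its p measures the spread between elements. Elements beyond the control range lay outside the controls' mean plus or minus 2 SD in both replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

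The named elements follow a rule fixed before the data were examined. At each day these are the 12 domain elements with the highest and the 12 with the lowest fold change among those past the threshold and on the same side of the control mean in both replicates, or, where none passed, among those beyond the control range. For the difference they are the 6 highest and 6 lowest past the threshold, and for each list the 2 members with the largest absolute change. For families they are the 5 with the smallest adjusted p in each direction. Elements are named by protein entry, Pfam domain and first residue, as in the tables; entry names were not mapped to gene positions. The 8 labels that join several elements were tested but belong to no list.

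On simulated counts at day 2 (5482 elements tested) edgeR recovered 0 of 67 elements changed by 1 on the log2 scale, 31 of 67 changed by 2 and 56 of 65 changed by 4, with 3 false calls among 5243. At day 10 (5408 elements tested) it recovered 8 of 67, 45 of 67 and 60 of 66, with 4 false calls among 5168. For the difference (5460 elements tested) it recovered 0 of 67, 7 of 67 and 41 of 66, with 1 false call among 5220. The simulated elements had 1 mean over all libraries, with unshifted controls, no effect of culture and 200 domains changed by these folds. In the data 205 of 480 random sequences, which enter the scaling, were lower at day 2. The false-call counts therefore do not carry over to the data. Alternatives covered other scalings, DESeq2 1.42.0, other filters, a minimum fold of 1.5, no replicate block and each replicate left out. Scaling over DMD tiles alone or random sequences alone, leaving out elements at the count floor, and lists limited to the authors' table were chosen after seeing the data.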

Results

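The screen measured how strongly each nuclear domain of a large library, fused beside a KRAB domain, left a reporter silenced in K562 cells. There were 4 groups of 2 libraries, the bound and unbound fractions at day 2 and at day 10, with total counts from 3896291 to 5760478. Negative controls were random sequences and tiles of dystrophin, the product of the DMD gene (chromosome X, 31119222 to 33339388 in GRCh38.p14). All elements also carried KRAB, so the controls show silencing by KRAB beside a sequence not chosen for a nuclear function.

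At day 2 the comparison asks which partner domains shift silencing by KRAB. The lowest elements included J domains, which stimulate Hsp70 chaperones. DJB12_HUMAN DnaJ 100 had a log2 fold change of -6.42 ± 0.54 (SE, n = 2) and DJB14_HUMAN DnaJ 98 of -6.40 ± 0.54. PCGF5_HUMAN RAWUL 152, from a Polycomb protein, was at -6.48 ± 0.54 and RPB2_HUMAN RNA_pol_Rpb2_3 460, from a large subunit of RNA polymerase II, at -6.37 ± 0.56. The highest elements were MEX3B_HUMAN KH_1 58, an RNA-binding domain, at 5.54 ± 1.28, SPAG7_HUMAN R3H 37 at 5.12 ± 1.24 and ZN182_HUMAN KRAB 6 at 5.07 ± 1.25.

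Among the 12 lowest, which lay between -6.48 and -6.14, were also DHX16_HUMAN OB_NTP_bind 937 from an RNA helicase, CEPT1_HUMAN CDP-OH_P_transf 80 from an enzyme of phospholipid synthesis, and VGFR2_HUMAN VEGFR-2_TMD 736, the membrane-spanning segment of a growth factor receptor. PASK_HUMAN PAS_9 338, NMES1_HUMAN B12D 2, ASPM_HUMAN IQ 1364, RN126_HUMAN zf-RING_2 208 from a ubiquitin ligase, and TAF5L_HUMAN WD40 395 completed them. Their edgeR adjusted p-values ran from 1.16e-29 to 4.28e-17, and none had a library at the count floor. With 1 residual degree of freedom, p-values this small rest on a spread shared across elements, not on that between 2 cultures. The smallest edgeR adjusted p of any domain was 0.000716 without the replicate block and 1.74e-11 with TMM over all elements. CEPT1_HUMAN CDP-OH_P_transf 80 took the largest share of the bound libraries, 2.93% and 3.07% of counts. In the authors' deposited table were 3 of the 12 lowest and 6 of the 12 highest. Of all lower domains 14 were in it and 208 were not. How well these fusions were expressed was not tested.

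The 12 highest lay between 4.32 and 5.54, with edgeR adjusted p-values from 0.000254 to 0.00316. Besides those named, they were SPAST_HUMAN Vps4_C 536, ZN521_HUMAN zf-C2H2_6 17, CELF3_HUMAN RRM_1 91, AN34B_HUMAN Ank_4 1, CBX7_HUMAN Chromo 1 from a Polycomb protein, HXB4_HUMAN Homeodomain 151, NOTO_HUMAN Homeodomain 145, SRGEF_HUMAN RCC1 1 and FOXP4_HUMAN FOXP-CC 297. In 10 of these 12 a library was at the count floor of 5, so the size of their fold changes depends on that floor.

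Over all 5495 tested elements, 586 were higher and 439 lower by edgeR. Of 4670 domain elements, 546 were higher and 222 lower. A library was at the count floor in 132 of the higher and 2 of the lower domains. The split depended on the scaling. TMM over all elements gave 37 higher and 521 lower, library totals 1929 and 399, TMM over DMD tiles alone 39 and 522, and TMM over random sequences alone 3688 and 331. The median fold change of all elements was 0.90 under the control scaling and 0.14 with TMM over all elements, so higher values are best read against 0.90. Without the replicate block 204 were higher and 377 lower, 581 in all.

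**Figure D1:**
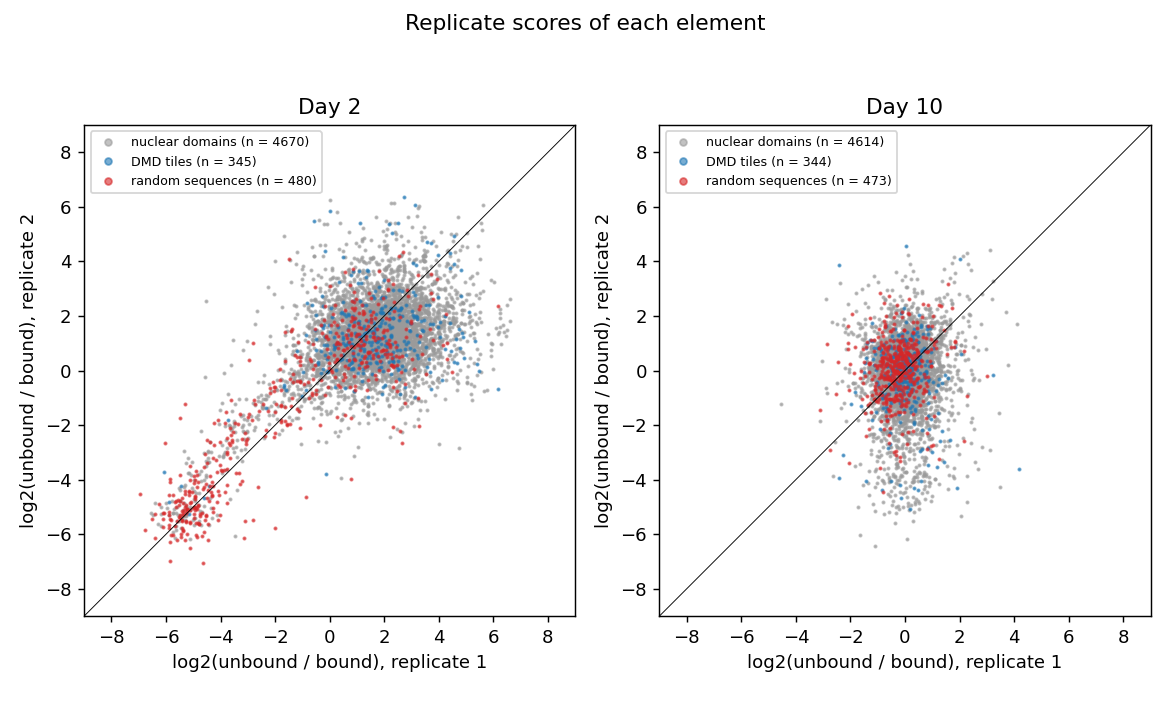
Log2 ratio of unbound over bound counts in replicate 1 (x axis) and replicate 2 (y axis) for each tested element at day 2 and day 10; grey points are domains, blue DMD tiles and red random sequences, and the line marks equal values. Across elements r was 0.669 at day 2 and 0.0596 at day 10.

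At day 2 Spearman's rho was 0.384 over all elements, and r was 0.238 over elements in the authors' deposited table. By count, r ran from 0.376 over the 1375 elements with the fewest counts to 0.929 over the 1374 with the most. These are day-2 counts, which rise with the shift itself, so the rise in r cannot be put down to depth alone.

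Random sequences had a mean log2 ratio of -1.36 ± 2.86 (SD, n = 480) at day 2 and DMD tiles of 1.44 ± 1.36 (SD, n = 345). The difference was -2.80 (permutation p = 1e-05, the smallest these resamples can give). This p is over elements of the same cultures and does not measure how cultures vary. In both replicates 219 of 480 random sequences lay below the lowest 5% of DMD tiles, or 45.6%, against 11 of 345 DMD tiles (3.19%) and 210 of 4670 domains (4.50%). At day 10 the means were -0.12 ± 0.72 (SD, n = 473) and -0.10 ± 0.74 (SD, n = 344), a difference of -0.02 (permutation p = 0.708), but the difference was -0.25 in replicate 1 and 0.22 in replicate 2.

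By list at day 2, RNA-binding domains had 62 of 335 members higher and none lower, with a median of 1.24 (limma camera adjusted p = 0.0014, and adjusted p = 0.701 with an estimated correlation), led by MEX3B_HUMAN KH_1 58 and CELF3_HUMAN RRM_1 91. C2H2 zinc fingers had 24 higher and 1 lower of 199, with a median of 1.32 (camera adjusted p = 0.00369, and adjusted p = 0.701 with an estimated correlation), with ZN595_HUMAN zf-C2H2_6 508 at 3.94 ± 1.10. Homeodomains, DNA-binding domains of developmental regulators, had 27 higher of 198 and a median of 1.64 (camera adjusted p = 0.00924, and adjusted p = 0.701 with an estimated correlation). PHD fingers, readers of histone tails, had 15 higher of 64 and a median of 1.19 (camera adjusted p = 0.00992, and adjusted p = 0.701 with an estimated correlation). CHD5_HUMAN PHD 400 was at 3.66 ± 1.16 and KMT2A_HUMAN PHD 1557 at 3.57 ± 1.14. In both, and in ZN595_HUMAN zf-C2H2_6 508, a bound library was at the count floor, so their sizes depend on it. A second KRAB domain gave 25 higher and 1 lower of 322 and a median of 1.16 (camera adjusted p = 0.022, and adjusted p = 0.725 with an estimated correlation). The share higher was smaller than over all elements (586 of 5495) and among DMD tiles (32 of 345). For C2H2 zinc fingers it was near that of all domains (546 of 4670), whose median was 0.98. The lower KRAB member was PRDM7_HUMAN KRAB 6 at -5.22 ± 0.51. Among elements of the authors' deposited table alone, an alternative chosen after seeing the data, the KRAB list turned direction (adjusted p = 0.801) and 0 of 14 lists passed. Random sequences had 8 higher and 205 lower of 480 (camera adjusted p = 3.26e-44, and adjusted p = 0.701 with an estimated correlation).

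Adjusted over the list alone, the higher and lower counts were 67 and 0 for RNA binding, 12 and 0 for C2H2 zinc fingers, 16 and 0 for homeodomains, 17 and 0 for PHD fingers, 6 and 1 for KRAB, and 14 and 213 for random sequences. With TMM over all elements the higher and lower counts were 3 and 3, 3 and 2, 3 and 1, 1 and 0, 2 and 2, and 0 and 220 in the same order, so for RNA binding and KRAB neither side then outnumbered the other.

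The remaining 13 lists did not pass at day 2, from adjusted p = 0.0595 for bZIP to 0.877 by camera. The bZIP list had 8 higher of 35, including DDIT3_HUMAN bZIP_2 84 at 4.19 ± 1.18. Activation domains had 4 higher and 2 lower of 24, and the lower members were HIF1A_HUMAN HIF-1 526 at -4.25 ± 0.51 and EPAS1_HUMAN HIF-1 493 at -3.80 ± 0.94, both oxygen-regulated segments. HP1 and Polycomb had 8 higher and 1 lower of 62, methyl-DNA binding and NuRD 1 and 1 of 32, and SUMO and ubiquitin 2 and 1 of 30. Helix-loop-helix domains had 11 higher and 2 lower of 107, led by TFE2_HUMAN HLH 536 at 4.13 ± 1.14. DDIT3_HUMAN bZIP_2 84, EPAS1_HUMAN HIF-1 493 and TFE2_HUMAN HLH 536 each had a library at the count floor, so their sizes depend on it. HMG boxes had 4 higher of 52 and nuclear receptors 5 higher of 45. Corepressor contacts had 2 higher and 1 lower of 12, bromodomains 0 and 1 of 3, and DMD tiles 32 and 12 of 345. With TMM over all elements the higher and lower counts were 2 and 0 for bZIP, 0 and 3 for activation domains, 1 and 2 for HP1 and Polycomb, 0 and 1 for methyl-DNA binding and NuRD, and 0 and 2 for SUMO and ubiquitin. They were 1 and 2 for helix-loop-helix domains, 0 and 0 for HMG boxes, 0 and 1 for nuclear receptors, corepressor contacts and bromodomains, and 4 and 14 for DMD tiles. No member of the histone methyltransferase list (4 measured) or the PWWP and Tudor list (3 measured) passed in edgeR.

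**Figure D2:**
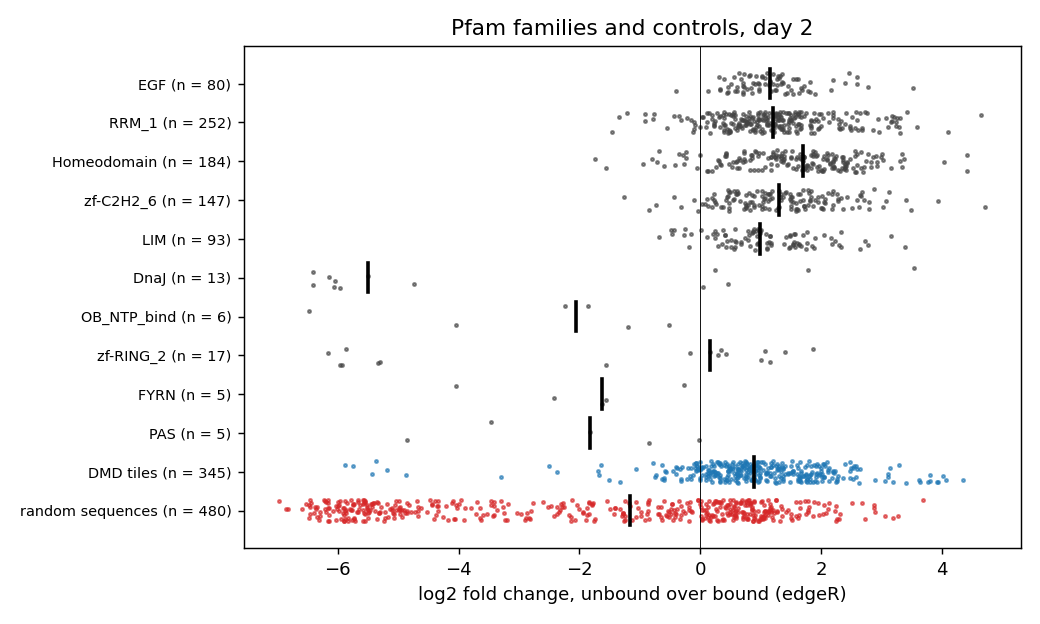
Log2 fold change of unbound over bound at day 2 (x axis, edgeR) for elements of the 5 Pfam families with the smallest adjusted p in each direction and for the controls; each point is an element and each black line a median. The DnaJ median was -5.50 and that of DMD tiles 0.89.

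Among 166 Pfam families at day 2, 14 passed by camera, 6 up and 8 down. None passed with an estimated correlation, which 1 residual degree of freedom hardly allows. J domains (DnaJ) had 8 of 13 elements lower and 1 higher, with a median of -5.50 (camera adjusted p = 7.92e-09, and adjusted p = 0.881 with an estimated correlation). OB_NTP_bind, a helicase-associated fold, had 4 of 6 lower, FYRN 4 of 5, PAS 3 of 5 and zf-RING_2 6 of 17. The zf-RING_2 median was 0.15 while its mean was -1.68. Over all domains 546 of 4670 were higher, with a median of 0.98, which was also the LIM median. The zf-C2H2_6 share was near that of all domains. EGF had 22 of 80 higher, RRM_1 50 of 252, Homeodomain 27 of 184, zf-C2H2_6 19 of 147 and LIM 16 of 93. With TMM over all elements, higher members numbered 0, 2, 3, 3 and 0 in these families, while DnaJ kept 8 lower. As sets, EGF and LIM did not pass with that TMM (adjusted p = 0.0613 and 0.169), nor LIM without the replicate block (0.0879). Without replicate 1, Homeodomain (0.383), zf-C2H2_6 (0.206) and LIM (0.136) did not pass, nor Homeodomain (0.243) and zf-C2H2_6 (0.0849) without replicate 2, in fits whose spread at day 2 comes from day 10. Against control elements alone, OB_NTP_bind (0.0555), PAS (0.171), FYRN (0.171) and zf-RING_2 (0.329) did not pass, while DnaJ did (0.0252).

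At day 10 the comparison asks which partners shift the silencing that remains after release. No element passed in edgeR: 0 of 5431, with 192 higher and 154 lower at an unadjusted p under 0.05, and DESeq2 also gave 0, with 197 and 172. KRAB elements had a median fold change of 0.44 over 320 members (camera adjusted p = 1.7e-06), bZIP elements of 0.79 over 30 (camera adjusted p = 0.000959) and homeodomains of 0.35 over 168 (camera adjusted p = 0.0393), against 0.05 for all elements. None of the 3 passed with an estimated correlation (camera adjusted p = 0.835), a test that 1 residual degree of freedom hardly lets any list pass. Adjusted over the list alone, 1 KRAB element was higher and no bZIP or homeodomain element passed in edgeR.

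Beyond the control range in both replicates lay 22 domain elements above and 4 below. Of the 12 highest, 5 were homeodomains: HXB9_HUMAN Homeodomain 170 at 4.0 ± 1.20, GSX2_HUMAN Homeodomain 191 at 3.24 ± 1.14, HXA10_HUMAN Homeodomain 325 at 3.12 ± 1.23, NKX32_HUMAN Homeodomain 195 at 3.02 ± 1.11 and MNX1_HUMAN Homeodomain 230 at 2.86 ± 1.12. The bZIP domains CREM_HUMAN bZIP_1 265 and ATF1_HUMAN bZIP_1 191, from related cyclic AMP response factors, were at 3.39 ± 1.19 and 2.96 ± 1.12. FA32A_HUMAN DUF1754 1 was at 3.46 ± 0.93, MTG8R_HUMAN NHR2 324 at 3.43 ± 1.13, ASCL3_HUMAN HLH 79 at 3.15 ± 0.88, TIGD4_HUMAN CENP-B_N 1 at 3.11 ± 1.12 and RBM7_HUMAN RRM_1 6 at 2.79 ± 1.05. In 3 of the 12 highest a library was at the count floor, all homeodomains (HXB9_HUMAN, HXA10_HUMAN and MNX1_HUMAN), as in 3 of the 4 below. The 4 below were PPID_HUMAN TPR_7 202 at -3.41 ± 1.21, ANM2_HUMAN SH3_1 18 at -3.24 ± 0.89, CREST_HUMAN SSXT 3 at -2.73 ± 1.18 and P5F1B_HUMAN Homeodomain 218 at -2.63 ± 1.14. Among KRAB elements ZN425_HUMAN KRAB 1 was at 2.98 ± 1.08 and ZN566_HUMAN KRAB 1 at 2.61 ± 1.09, neither past the threshold. The edgeR adjusted p-values of the 12 highest and the 4 below ran from 0.239 to 0.695. Above the range lay 1 of 473 random sequences (0.21%) and 1 of 344 DMD tiles (0.29%), against 0.48% of the 4614 domains. Below it lay 2 of each kind of control (0.42% and 0.58%), against 0.09% of domains. Domains thus lay below the range no more often than controls did. The unbound library of replicate 2 had 305 elements at the count floor, against 51 in replicate 1.

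**Figure D3:**
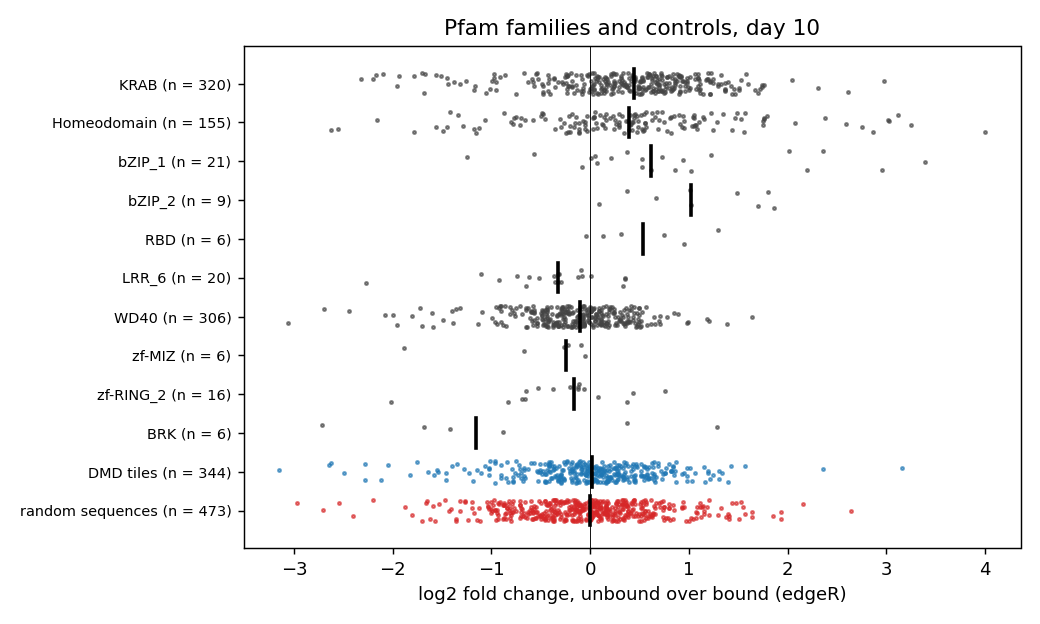
Log2 fold change of unbound over bound at day 10 (x axis, edgeR) for elements of the 5 Pfam families with the smallest adjusted p in each direction and for the controls; each point is an element and each black line a median. The KRAB median was 0.44 and that of DMD tiles 0.02.

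The other lists did not pass at day 10 by camera, from adjusted p = 0.183 for activation domains to 0.8 for bromodomains. Their medians ran from -0.30 for PWWP and Tudor to 0.22 for activation domains. Of 166 families KRAB alone passed (camera adjusted p = 1.49e-05, and adjusted p = 0.978 with an estimated correlation). Next came bZIP_2, bZIP_1 and Homeodomain, with medians of 1.02, 0.62 and 0.40 (camera adjusted p = 0.0917), and RBD at 0.53. On the other side LRR_6 had a median of -0.33 and WD40 of -0.11 (camera adjusted p = 0.059), followed by zf-MIZ at -0.25, zf-RING_2 at -0.16 and BRK at -1.16. Without replicate 1 the Pfam family KRAB at day 10 did not pass (camera adjusted p = 0.0924), in a fit where 1 bound and 1 unbound library remain at that day and the day-2 libraries supply the spread.

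The difference between days was tested per element. The most positive differences were in elements low at day 2. SYNE1_HUMAN KASH 8717, the nuclear-envelope anchor of a nesprin, was at 6.30 ± 1.0, TAF5L_HUMAN WD40 395 at 5.83 ± 0.50 and DJB12_HUMAN DnaJ 100 at 5.75 ± 0.56. MDN1_HUMAN AAA_5 2053 was at 5.74 ± 0.49, DNJB6_HUMAN DnaJ 1 at 5.65 ± 1.5 and CEPT1_HUMAN CDP-OH_P_transf 80 at 5.64 ± 0.47. Over all elements the SD of fold changes was 1.80 at day 2 and 0.72 at day 10. These differences thus largely restate the low day-2 values, and no gain of silencing follows from them. The most negative were ANM2_HUMAN SH3_1 18 at -7.53 ± 1.64, ZN521_HUMAN zf-C2H2_6 17 at -7.47 ± 1.93, COMD5_HUMAN COMM_domain 142 at -6.24 ± 1.63, NOTC4_HUMAN Notch 1145 at -6.23 ± 1.72, ZN595_HUMAN zf-C2H2_6 508 at -5.94 ± 1.5 and CASL_HUMAN SH3_9 1 at -5.77 ± 1.64. All 6 of the most negative had a library at the count floor, and none of the 6 most positive did. The most negative also had lower day-10 ratios in replicate 2 than in replicate 1. The gap was smallest for ZN595_HUMAN zf-C2H2_6 508 (-0.81 in replicate 1 and -2.81 in replicate 2). It was largest for ZN521_HUMAN zf-C2H2_6 17 (-0.21 and -5.09), so the day-10 part of their differences rests mainly on replicate 2. The day-2 part does not: their day-2 ratios lay 2.69 to 5.62 above the control mean across both replicates. Among the list members with the largest absolute changes, those past the threshold included PCGF5_HUMAN RAWUL 152 at 5.15 ± 0.52 and HIF1A_HUMAN HIF-1 526 at 4.04 ± 0.58. They also included MEX3B_HUMAN KH_1 58 at -5.60 ± 1.24, ZN182_HUMAN KRAB 6 at -5.41 ± 1.36 and CR3L3_HUMAN bZIP_1 232 at -5.35 ± 1.33. Each of these negative values rests on a day-2 bound library at the count floor. The edgeR adjusted p-values of the 12 most extreme ran from 1.54e-05 to 0.0468.

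Over 5463 elements, 303 were higher at day 10 and 166 lower by edgeR. TMM over all elements gave 392 and 9, library totals 301 and 769, DESeq2 401 and 375, TMM over DMD tiles 408 and 7, and TMM over random sequences 258 and 2903. The median of all elements was -1.06 under the control scaling and -0.13 with TMM over all elements. Without day 10 replicate 2 the counts were 283 higher and 6 lower.

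RNA-binding domains had 16 of 335 members lower (median -1.38, camera adjusted p = 0.00516, and adjusted p = 0.911 with an estimated correlation), C2H2 zinc fingers 7 of 200 (median -1.53, camera adjusted p = 0.0414, and adjusted p = 0.911 with an estimated correlation) and PHD fingers 6 of 64 (median -1.27, camera adjusted p = 0.0459, and adjusted p = 0.769 with an estimated correlation). Random sequences had 144 higher and 1 lower of 477 (median 0.79, camera adjusted p = 2.5e-39, and adjusted p = 0.0979 with an estimated correlation). With TMM over all elements the higher and lower counts were 1 and 1 for RNA binding, 0 and 0 for C2H2 zinc fingers, 0 and 1 for PHD fingers and 181 and 0 for random sequences. Adjusted over the list alone, the lower counts were 0 for RNA binding, 0 for C2H2 zinc fingers and 10 for PHD fingers by edgeR, and random sequences had 176 higher and 10 lower. The other lists did not pass by camera.

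In the authors' deposited table, 7 elements are called as enhancing KRAB at day 2 and 10 as impairing it. The authors' calls of both days come from this same screen, so a shared side is no separate check. All 17 were on the same side here, and all 17 passed in edgeR. At day 10 the authors' deposited table calls 20 as enhancing and 1 as impairing. These 21 were on the same side here and none passed in edgeR, while 15 of the 20 and the 1 had an unadjusted p under 0.05.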

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

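The tests on J domains and on random sequences were chosen after the results were seen; those on counts and the floor at day 10 were not.

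The effect of bound against unbound differed between the days for 469 elements by the test of the difference itself. By list, at a preset correlation, it differed for C2H2 zinc fingers (median -1.53), PHD fingers (-1.27), RNA binding (-1.38) and random sequences (0.79), beside a median of -1.06 for all elements. None passed with an estimated correlation, where 2 residual degrees of freedom hardly allow it. The camera adjusted p was then 0.911 for C2H2 zinc fingers and RNA binding, 0.769 for PHD fingers and 0.0979 for random sequences. By element it held for SYNE1_HUMAN KASH 8717 (6.30), TAF5L_HUMAN WD40 395 (5.83), DJB12_HUMAN DnaJ 100 (5.75), MDN1_HUMAN AAA_5 2053 (5.74), DNJB6_HUMAN DnaJ 1 (5.65) and CEPT1_HUMAN CDP-OH_P_transf 80 (5.64). In the other direction ANM2_HUMAN SH3_1 18 (-7.53), ZN521_HUMAN zf-C2H2_6 17 (-7.47), COMD5_HUMAN COMM_domain 142 (-6.24), NOTC4_HUMAN Notch 1145 (-6.23), ZN595_HUMAN zf-C2H2_6 508 (-5.94) and CASL_HUMAN SH3_9 1 (-5.77) passed. Each of these had a lower day-10 ratio in replicate 2 than in replicate 1 and a library at the count floor. Of all 166 elements lower in the difference, 9 stayed lower with TMM over all elements.

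J domains lay low at day 2. Whether noise of few counts plays a part was not decided. A first test, on their smaller day-10 counts (median 424, range without the extremes 87 to 1074), was undecided. Then r between replicates over the 13 J domains was taken, at 0.970 (95% interval 0.901 to 0.991). The family was picked for low values over the same 2 replicates, so a high r was likely beforehand and excludes nothing. It shows only that both cultures gave the same split. Poor expression of the fusion stays open, because the 6 J domains in the authors' table, where the lowest stability score is -0.50, split, with a median 0.55 SDs of the DMD tiles below theirs (-0.547) and a range without the extremes from -4.69 to -0.322. Of those 6, 2 were lower in edgeR, against 6 of the 7 outside the table. No biological explanation was tested.

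The replicates did not order elements alike at day 10 (r = 0.0596). Elements at the count floor are not the cause, since r was 0.0879 without them (95% interval 0.0608 to 0.115). Few counts stay open: r was 0.186 in the 1358 elements with the most counts (95% interval 0.134 to 0.237), which spans the bound of 0.20 set beforehand. Counts are reads, so the number of cells behind each element was not tested.

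Random sequences lay below DMD tiles at day 2. Noise of few counts would not be shared by separate cultures. Between replicates r over the 480 random sequences was 0.878 (95% interval 0.856 to 0.897), so both cultures ordered the random sequences largely alike. This r was chosen after its value was seen and does not measure the difference from DMD tiles. It is therefore no test of the cause. The first test left the question undecided. It took elements with at least 500 counts in each replicate at day 10 (157 random sequences and 200 DMD tiles). There the difference was -2.36, or 84.4% of that over all elements (95% interval 67.4% to 101%). Poor expression of the fusion cannot be told apart from an effect of the sequence, because 0 random sequences have a stability score in the authors' table.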

How the results depend on the processing

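Depth, 2 replicates and the choice of control elements limit these results. All 24 named day-2 elements kept their direction and side of the threshold in each alternative that tested them, as did the 16 at day 10; for the 12 of the difference, 23 values lost the threshold and 139 did not. Scaling over DMD tiles or random sequences alone and lists within the authors' table were chosen after seeing the data. The cause of the changes below was not tested. Fits without a replicate leave 1 bound and 1 unbound library at that day and take the spread from the other libraries, assuming that the lone ones vary alike, so their counts are not on the footing of fits within a day.

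At day 2, 1025 elements passed: 558 with TMM over all elements, 2328 with library totals, 581 without the replicate block, 561 with TMM over DMD tiles, 4019 with TMM over random sequences, 1896 with all 8 libraries, and 1342 to 2057 without a replicate. Domains higher numbered 33, 1771, 193, 35, 3330 and 1380 in the same order, 260 at a minimum fold of 1.5, and 925 to 1469 without a replicate. Domains lower numbered 147 with TMM over random sequences and 168 to 256 without a replicate. At day 10, where 0 passed in edgeR (192 higher and 154 lower at an unadjusted p under 0.05, 0 in DESeq2), 2 passed without the low-count filter and 2 with at least 50 counts, all domains lower; without a replicate 0 to 7 passed, of which 0 to 6 were domains lower.

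For the difference, 469 passed: 1070 with library totals, 776 with DESeq2, 3161 with TMM over random sequences, and 289 to 1374 without a replicate. Domains lower numbered 7 with TMM over all elements, 717 with library totals, 345 with DESeq2, 77 at a minimum fold of 1.5, 6 with TMM over DMD tiles, 2644 with TMM over random sequences, and 6 to 903 without a replicate.

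Beyond the control range at day 2 were 0 domains: 88 with the median and robust SD, 12 for the mean of replicates, 8 with random controls, 145 with DMD controls, 2 with a pseudocount of 5, and 28 to 30 without a replicate. At day 10 there were 26: 40 with the median and robust SD, 5 at 3 SD, 276 for the mean of replicates, and 196 to 280 without a replicate.

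Of the lists, 6 passed at day 2, 3 at day 10 and 4 for the difference. With an estimated correlation, a test that hardly any list could pass, 0, 0 and 0 passed. Against control elements alone 12, 8 and 11 did. Among elements of the authors' table, none passed at day 2 (0 of 14 lists) and 1 for the difference, and KRAB turned direction in both (adjusted p = 0.801 at day 2 and 0.000926 for the difference). Without a replicate, 4 lists passed at day 2, 2 to 5 at day 10 and 2 to 3 for the difference. Of the families, 14 passed at day 2 and 1 at day 10: 0 and 0 with an estimated correlation, 62 and 4 against control elements alone, 5 at day 10 with TMM over all elements, and without a replicate 7 to 12 at day 2 and 1 to 3 at day 10.

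Replicate agreement at day 2 was r = 0.690 with a pseudocount of 5. Random sequences minus DMD tiles at day 10 was 0.22 without replicate 1 and -0.25 without replicate 2, so its sign differed between the cultures. Without the replicate block, DMD tiles higher at day 2 numbered 9 rather than 32, random sequences higher at day 2 numbered 2 rather than 8, and elements lower at day 10 at an unadjusted p under 0.05 numbered 62 rather than 154. The naive library and the alternatives for files that give scores only were not run.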

Other observations

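All tests in this part were chosen after the results were seen.

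KASH domains, which anchor nesprins in the nuclear envelope, were lower at day 2 in 4 of 4 elements, with a median of -5.78. This group was chosen for its values, so no test of it is given. Domain elements outside the authors' table had a median log2 ratio of 1.15 ± 1.81 (SD, n = 2110) at day 2, against 1.69 ± 0.93 (SD, n = 2560) for those in it, and 208 of the former were lower in edgeR against 14 of the latter.

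A hypothesis was that hydrophobic elements silence less at day 2. By the hydropathy score of the authors' deposited table, the highest of 4 equal bins lay -0.34 from the lowest, with means of 1.5 (n = 639) and 1.85 (n = 641). The difference was -0.36 in replicate 1 and -0.32 in replicate 2. These are the elements and values whose Spearman's rho of -0.13 (n = 2555) gave the hypothesis, so the comparison is no test apart from it, and the hypothesis stays open.

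A second hypothesis was that domains that silence alone add to silencing at day 10. The 7 non-KRAB elements with a day-13 mean above 2 in the authors' deposited table differed by 0.16 from 2267 others (permutation p = 0.467), with -0.01 in replicate 1 and 0.32 in replicate 2, so 7 elements leave it open.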
